A study of Mus musculus with 4 samples.

How the data were processed

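The series holds RNA sequencing of sorted Ret-EGFP-positive cells from mouse dorsal root ganglia, with 1 female and 3 male libraries, each from 1 animal. Per the labels' protocols, cells were sorted into TRIzol LS, and 10 ng of RNA was amplified with the SMARTer Ultra Low Input kit over 12 PCR cycles and sequenced on an Illumina HiSeq instrument. The genotype label reads as a Ret-EGFP transgene, whereas the design text describes EGFP inserted at the Ret locus. All libraries carry the stage P2, and the labels of pool size and treatment say embryo for male B and male C and P2 mouse for female A and male A. These labels were used as a batch ("pool description"). Whether they mark a difference of age, library batch or colony is not given in the sources used here.

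The deposited count values are reads per gene, assigned with featureCounts 1.4.5 of the Subread package to GRCm38.p2, per the submitters' processing notes. The deposited CPM values are the counts divided by the library's total of gene counts, as recomputed here from the counts. The deposited RPKM values are, per the file headers and as recomputed here, the CPM divided by the gene's exon length in kilobases. The aligner, the annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here. The files list 41388 Ensembl genes, of which 40254 (97.3%) were given a symbol from GENCODE M21 (GRCm38).

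The libraries held between 17388493 and 28066448 gene counts (93.0 M in all). A count of 0 in the female library was set to a floor of 3 counts for a bound on its ratio, and ratios with 1 to 3 counts are given with a counting interval. The floors of 3 counts lay between 0.107 and 0.173 CPM before scaling. Levels are CPM scaled by TMM factors between 0.959 and 1.05, given as mean and SD over the 3 males. CPM per kilobase of exon length was the alternative for the order of genes in a list.

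The female library was tested against the 3 males with the edgeR 4.0.16 quasi-likelihood F test in R 4.3.3, with TMM scaling, filterByExpr (minimum count 10, minimum total 15) and Benjamini-Hochberg adjustment at 0.05. The lone female was assumed to vary like the males (2 residual degrees of freedom), whose spread holds the difference between the pool descriptions. Alternatives fixed before the data were examined were relative log expression size factors, no filter, a mean of at least 5 CPM, each male left out in turn, the pool description as a term (1 residual degree of freedom), DESeq2 1.42.0, limma-voom (limma 3.58.1) and robust empirical Bayes. Offsets for GC content and transcript length, fitted per library with mgcv 1.9.3, were added after the data were seen, alone and together with the pool description. So was the comparison of the P2-mouse pair with the embryo pair, which used the same test, with sex as a term and each library left out among its alternatives. Each library was also set against the other 3, and the 4 libraries were parted into pairs in every way. The SE of a gene's edgeR log2 fold change is its size over the square root of the F statistic. This SE rests on a spread moderated across genes, not on that gene's libraries alone.

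Before the data were examined, 31 gene lists were fixed, and those with at least 3 tested members were tested with camera (preset correlation 0.01), camera with an estimated correlation, and fry. They cover Y-linked genes, X-inactivation escape, the GDNF receptors and ligands, Trk and p75 receptors, 8 sets of sensory neuron, channel and receptor genes, sex hormone receptors, sympathetic neurons, 8 sets of other cell types, immediate early genes, injury and regeneration, proliferation, mitochondrially encoded, ribosomal, oxidative phosphorylation, synaptic vesicle and axon guidance genes. The GDNF ligand and spinal cord lists had too few tested members and are given as levels. In the comparison of the pairs the skeletal muscle list dropped out too.

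Genes were named by a rule. It took the Y-linked and X-escape lists, the 10 largest rises and falls with a mean of at least 5 CPM that passed the test with the female outside the male range (none passed), Ret and the 4 most abundant members of each list, up to 4 members of a list per direction that passed the test, and the 10 most abundant genes. The same rule was applied to the comparison of the pairs. Some genes that the rule takes are not reported here.

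Words of 50 bases shared between annotated transcripts were counted for 636 genes, of which 35 shared over 50%. No genome sequence was used. The tests were checked on simulated data with 50 genes changed at each fold. At a fold of 4, the female test recovered 46% of changed genes, the test with the pool description as a term 90% and the test between the pairs 100%. At a fold of 2 the shares were 0%, 16% and 74%. Of unchanged genes 5 of 15904, 18 of 15865 and 17 of 14950 were called. In the simulations of the female tests the libraries held no difference between the pairs, unlike the real counts. The shares recovered there need not hold for the female tests of the real counts. A planted GC trend with a Spearman's rho of -0.832 was brought to -0.107 by the offsets, and the calls it caused fell from 2789 to 0 (15014 genes). No gene was changed there, so this cannot show whether the offsets spare real differences that run with GC content or length. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.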

Results

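Ret encodes the receptor tyrosine kinase that responds to ligands of the glial cell line-derived neurotrophic factor (GDNF) family, and it marks several classes of sensory neuron in the dorsal root ganglion. RNA was measured in EGFP-positive cells sorted by flow cytometry from ganglia of mice with an EGFP reporter of Ret expression, labelled postnatal day 2. There were 4 libraries, 1 female (female A) and 3 male (male A, male B and male C), each from 1 animal. The pools held 20 ganglia for each male and 40 for the female. Gene counts summed to 28066448 in female A, 17388493 in male A, 22668371 in male B and 24901520 in male C. Between 20551 and 22269 genes had at least 1 count. The libraries carried no molecular identifiers, so count-based intervals and floors cover counting error only.

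The stage label was the same for every library, but the descriptions of the pools were not. They named a P2 mouse for female A and male A, and an embryo for male B and male C. Libraries that shared a pool description resembled each other more closely than libraries of the same sex. Over 13490 genes, which are not independent replicates, the correlation of log2 CPM was 0.991 between female A and male A and 0.986 between male B and male C. It lay between 0.933 and 0.943 for the 4 other pairs. The labels name each library as a separate sample, and each was counted as such.

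The sorted cells expressed Ret (ENSMUSG00000030110, chromosome 6, 118151748 to 118197744, GRCm38) at 252 ± 29.2 CPM in the males (SD, n = 3) and 222 CPM in the female. Among the GDNF co-receptors, Gfra3, the receptor subunit for artemin, was the most abundant at 377 ± 137 CPM in the males, followed by Gfra2 at 81.9 ± 30.4 CPM. Genes for the ligands themselves (Gdnf, Nrtn, Artn and Pspn) summed to 0.510 CPM or less in each library. The most abundant transcripts were those of cytoskeletal and growth-associated genes. Dpysl2, which encodes a microtubule-binding protein of growing axons, stood at 14315 ± 3825 CPM, Actb at 10178 ± 1733 CPM, the G protein subunit gene Gnb1 at 9663 ± 3505 CPM and Tuba1a at 7646 ± 1510 CPM (SD, n = 3 males). Stmn2, Tmsb4x, Map1b and Tubb5 also stood high, between 4792 and 6072 CPM. Gm42418, at 6812 ± 1524 CPM, shared 94.95% of its 50-base words with other annotated genes and is uncertain, as is Tuba1a, which shared 75.5%.

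Markers of nociceptors were abundant. Calca, the gene of the neuropeptide CGRP, reached 2459 ± 1040 CPM in the males and the substance P precursor gene Tac1 985 ± 363 CPM. Of the markers of nonpeptidergic nociceptors, the sodium channel gene Scn11a stood at 630 ± 35.7 CPM, Mrgprd at 363 ± 92.9 CPM and the ATP receptor gene P2rx3 at 312 ± 103 CPM. The sodium channel gene Scn10a and the mechanosensitive channel gene Piezo2 led the list of somatosensory channels at 830 ± 170 and 566 ± 67.2 CPM. Of the other receptor genes, Ngfr, which encodes the p75 receptor, stood at 139 ± 84.8 CPM, Sort1 at 33.3 ± 7.46 and Ntrk2 at 32.8 ± 12.1 CPM. Among markers of C-fibre low-threshold mechanoreceptors, Fam19a4 reached 210 ± 30.0 CPM and Th 14.9 ± 5.81 CPM. The neurofilament gene Nefh (138 ± 70.3 CPM) and Etv1 (129 ± 10.4 CPM) led the markers of myelinated mechanoreceptors and proprioceptors. Members of the itch neuron list were low, with Nts at 16.9 ± 4.84 and Nppb at 2.14 ± 1.03 CPM. The itch-related receptor gene Mrgpra3, held in the nonpeptidergic list, stood at 92.3 ± 46.0 CPM. The opioid and cannabinoid list was led by the cannabinoid receptor gene Cnr1 at 88.5 ± 3.75 CPM, and the list of sex hormone receptors by Gper1 at 21.0 ± 10.8 CPM.

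Transcripts of other cell types were present at unequal levels. The 13 markers of myelinating Schwann cells summed to 3118 CPM in male B and 3131 in male C, against 7534 in male A and 4622 in female A. Their most abundant member was Pmp22 (3036 ± 903 CPM, SD, n = 3 males), which weighs heavily in these sums. The median level of the 13 was 12.0 CPM in male B, 16.4 in male C, 132 in male A and 87.9 in female A. The 10 fibroblast markers summed to 350 and 383 CPM in male B and male C, and to 1672 and 1501 CPM in male A and female A. Satellite glia markers summed to between 957 and 1675 CPM and endothelial and mural markers to between 99.1 and 106 CPM. Macrophage, erythroid, skeletal muscle, sympathetic neuron and spinal cord markers each summed to 55.0 CPM or less in every library. CPM is not scaled to gene length. With CPM per kilobase, 57 of the 124 genes listed by level changed their position within their list.

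The series set male against female sensory neurons. The genes that set the female library apart were those of the sex chromosomes. The Y-linked RNA helicase gene Ddx3y had 2 counts in the female library and 96.4 ± 66.5 CPM in the males (SD, n = 3). The ratio of the pooled male counts to the female counts, each over its scaled library size, was 1330 (95% counting interval 368 to 10981). For the translation initiation factor gene Eif2s3y, with 1 count in the female, the males stood at 60.6 ± 47.1 CPM and this ratio of pooled counts was 1660 (interval 298 to 65568). The demethylase family gene Uty had 2 counts in the female and 37.3 ± 18.2 CPM in the males, with a ratio of pooled counts of 528 (interval 146 to 4360). Kdm5d, which encodes a histone demethylase, had no count in the female and 11.4 ± 2.52 CPM in the males, at least 112-fold higher than the floor of 3 counts in the female library (0.102 CPM). Xist, the noncoding RNA that silences an X chromosome, stood at 222 CPM in the female and at 0.778, 0.138 and 1.84 CPM in male A, male B and male C.

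The Y-linked genes Usp9y, Zfy1 and Zfy2 had at most 3 counts in any library. Ddx3y (ENSMUSG00000069045), Eif2s3y (ENSMUSG00000069049), Uty (ENSMUSG00000068457) and Kdm5d (ENSMUSG00000056673) all lie between 897788 and 1286629 on chromosome Y. Xist (ENSMUSG00000086503) lies at 103460375 to 103483217 on chromosome X. Of the other genes known to escape X inactivation, Kdm6a stood at 47.0 CPM in the female and 22.5 ± 8.73 CPM in the males, Kdm5c at 54.5 and 41.0 ± 1.68, Eif2s3x at 11 and 6.36 ± 2.56, and 5530601H04Rik at 41.7 and 27.5 ± 4.81. The values for Ddx3x were 253 CPM in the female and 245, 79.5 and 78.3 CPM in male A, male B and male C. Pbdc1 (71.4 and 59.5 ± 5.35 CPM) and Utp14a (25.5 and 20.6 ± 5.16 CPM) also lay above the male mean. Male A alone had 32.3 CPM of Kdm6a, 39.3 of Kdm5c, 9.28 of Eif2s3x and 33.0 of 5530601H04Rik. It had 65.7 CPM of Pbdc1 and, above the female, 25.8 of Utp14a.

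**Figure D1:**
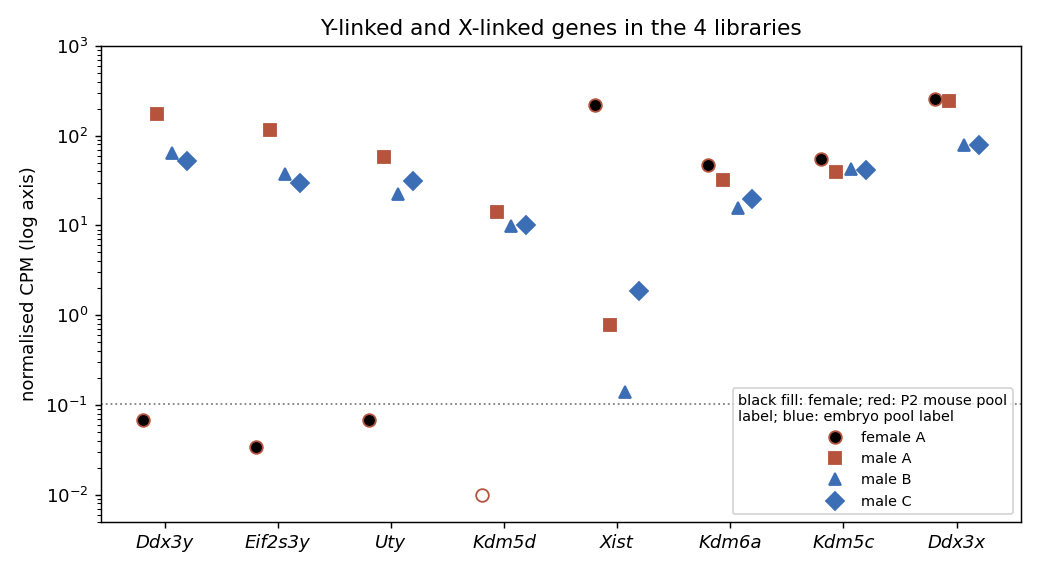
Normalised CPM (log axis) of 4 Y-linked and 4 X-linked genes in each of the 4 libraries, with the floor of 3 counts in the female library (0.102 CPM) as a dotted line and a count of 0 drawn as an open circle. Female A lies under the floor for the 4 Y-linked genes and at 222 CPM for Xist, against 1.84 CPM or less in the males.

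Over all 16708 genes tested, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes higher and 0 lower in the female library, with 129 genes at an unadjusted p under 0.05. The smallest adjusted p was 0.746, for Kdm5d. limma-voom also called 0. DESeq2 called 5, namely Xist higher and Ddx3y, Eif2s3y, Uty and Kdm5d lower. Adjusted over the list alone, the edgeR test called these 4 of the 4 tested Y-linked genes (adjusted p between 0.000179 and 0.000649) and Xist of the 8 genes of the X list (adjusted p = 0.00135). Adjusted over all genes tested, neither list had a gene called. The female is a single library, so the test assumed that females vary like the 3 males. Those males mix both pool descriptions, so their spread holds the difference between the pairs. The median coefficient of variation that edgeR estimated between libraries was 0.36, against 0.19 with the pool description as a term. The lack of calls therefore does not show that the sexes are alike.

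With the pool description as a term, the female was set against male A, and the edgeR test called 0 genes higher and 4 lower (270 at an unadjusted p under 0.05). The genes called were Ddx3y (adjusted p = 0.00104), Eif2s3y (adjusted p = 0.00145), Uty (adjusted p = 0.00695) and Kdm5d (adjusted p = 0.0148). Xist had a log2 fold change of 8.15 (SE 0.995) and an edgeR adjusted p of 0.496 there, and 7.89 (SE 0.946) without the term. The value for Ddx3x moved from 0.92 without the term to 0.05 with it, and that for Kdm6a from 1.06 to 0.54. For Ret it was -0.18 without the term and -0.01 with it. The pools described as embryo held males only, so no within-description value could be had for them. Leaving out male A makes sex and pool description the same contrast. Without male A, which left the female against male B and male C, 1935 genes were called higher and 1681 lower. Without male B the counts were 1 and 4, and without male C 1 and 6, the genes beyond Xist and the 4 Y-linked ones being Chodl and Tpsb2. Tpsb2 was named after its value was seen.

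Of the 29 gene lists with at least 3 tested members, camera with a preset correlation called 11 between the female and the male libraries, 6 higher and 5 lower. No call held with an estimated correlation (smallest adjusted p = 0.440, for the Y-linked list), and fry called 0 lists (smallest adjusted p = 0.738). The lists called higher were X-inactivation escape, Schwann cell, fibroblast, endothelial and mural, immediate early and mitochondrially encoded genes. Those called lower were the Y-linked, peptidergic nociceptor, myelinated mechanoreceptor and proprioceptor, skeletal muscle and nuclear oxidative phosphorylation genes. Their medians without and with the pool description as a term were 0.69 and 0.29 for X escape, 0.95 and -0.08 for fibroblast, 1.11 and 0.90 for endothelial and mural, and 0.41 and -0.12 for mitochondrially encoded genes. They were -0.77 and -0.09 for peptidergic nociceptor, -0.47 and 0.04 for myelinated mechanoreceptor and proprioceptor, -1.14 and -0.44 for skeletal muscle and -0.33 and 0.00 for oxidative phosphorylation genes. The 18 lists not called had medians between -0.65 (sex hormone receptors) and 0.67 (erythroid), with camera adjusted p between 0.0727 and 0.969. No member of a list other than the sex-linked ones passed the edgeR test, over all genes or adjusted over the list alone. With the pool description as a term, 6 lists were called. They were the Y-linked (adjusted p = 7.96e-28) and X-escape lists (0.00262), the Schwann cell list, now lower in the female (median log2 fold change -0.63 against 0.36 without the term), the immediate early list, also now lower (-0.23 against 0.47), proliferation (-0.26) and the synaptic vesicle list (0.17 against -0.14). With an estimated correlation each of these 6 had an adjusted p of 0.874. Adjusted over the list alone, 4 of the 13 Schwann cell genes were lower in the female than in male A. With this term 1 library stands against 1, and the spread (1 residual degree of freedom) comes from male B against male C alone, so these calls compare the libraries, not the sexes.

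The libraries parted far more by pool description than by sex. Relative to the pair described as embryo (male B and male C), the pair described as P2 mouse (female A and male A) had higher levels of Schwann cell, fibroblast and immediate early genes. It had lower levels of many neuronal genes, among them Tubb3, Calca, Calcb and Gfra2. The periaxin gene Prx stood at a mean of 110 CPM in the P2-mouse pair and 15.6 CPM in the embryo pair, the collagen gene Col3a1 at 431 and 45.4 CPM, and the neuronal tubulin gene Tubb3 at 1866 and 5575 CPM. The comparison of these pairs was added after the data were seen. It rests on 2 libraries in each pair, and the P2-mouse pair alone holds the female.

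The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 3472 of 15568 genes higher and 3112 lower in the P2-mouse pair. The other ways of parting the 4 libraries into pairs called 0 genes each, with 20 and 37 at an unadjusted p under 0.05. With sex as a term, which removes the female from the comparison, 2064 genes were higher and 1615 lower. Without female A the counts were 2202 and 1834, and without male A 1935 and 1681. The fit without male A is the one given above for the female against male B and male C. Sex and pool description cannot be told apart in it. The fold changes between the full pairs ran with the composition of the transcripts. Spearman's rho across 15474 genes was -0.444 with GC content and 0.275 with transcript length. After offsets for both, 2151 genes were higher and 2883 lower, and 3935 of the 6554 calls among these genes (60.0%) were kept in the same direction. Of 28 lists tested, camera with the preset correlation called 13, with an estimated correlation 0. The rotation test fry called 8, the peptidergic, pan-sensory, GDNF receptor, oxidative phosphorylation and ribosomal lists lower and the fibroblast, mitochondrially encoded and injury lists higher (smallest adjusted p = 0.00702). Schwann cell (adjusted p = 0.0688) and immediate early genes (0.0521) were not called by fry, and with sex as a term fry called the mitochondrially encoded list alone (0.0305).

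The neuronal genes that fell belonged to several classes. Of the 10 peptidergic nociceptor genes, 5 were lower in the P2-mouse pair, namely Calcb, the gene of a second CGRP peptide (-1.86, SE 0.087), the neuropeptide gene Gal (-1.52, SE 0.095), Calca (-1.28, SE 0.078), Tac1 (-1.07, SE 0.092) and the capsaicin receptor gene Trpv1 (-0.92, SE 0.12). Their edgeR adjusted p lay between 9.99e-05 and 0.000905. The list's median log2 fold change was -0.99 (camera adjusted p = 2.15e-05, and 0.473 with an estimated correlation). The estimated correlation was -0.074, below the preset 0.01, so the higher adjusted p came from the few residual degrees of freedom. Of 17 pan-sensory genes 11 fell and 2 rose, with a median of -0.54 (camera adjusted p = 0.00461; adjusted p = 0.473 with an estimated correlation). Tubb3 fell by 1.58 (log2), the actin-binding protein gene Avil by 0.92, Uchl1 by 0.82 and the intermediate filament gene Prph by 0.61, while the pain-related sodium channel gene Scn9a was higher at 0.86. With the GC and length offsets Uchl1 (-0.25, SE 0.095), Prph (-0.19, SE 0.11) and Scn9a (0.02, SE 0.091) were not called, while Gal stood at -0.999 and Avil at -0.56. Slc17a6, the vesicular glutamate transporter gene, was called higher at 0.26 and stood at -0.21 with these offsets, where it was not called.

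Among the GDNF receptor genes, Gfra2 (-1.06, SE 0.12), Gfra3 (-0.91, SE 0.11) and Gfra1 (-0.56, SE 0.12) were lower in the P2-mouse pair, with edgeR adjusted p between 0.000415 and 0.00832. With the GC and length offsets Gfra3 stood at -0.43 (SE 0.090) and was still called. Ret itself did not pass (-0.25, SE 0.094, adjusted p = 0.0660). With the GC and length offsets Ret stood at -0.32 (SE 0.098) and was called lower (edgeR adjusted p = 0.0367). With them 5 of the 6 genes were lower. The median of the 6 genes of the list was -0.40 (camera adjusted p = 0.0362; adjusted p = 0.473 with an estimated correlation). The median was -0.39 without male A (camera adjusted p = 0.0618), -0.44 with the GC and length offsets (0.0596) and -0.54 with only genes of at least 5 CPM (0.0541). Of 14 tested markers of myelinated mechanoreceptors and proprioceptors 7 fell and 2 rose (median -0.72, camera adjusted p = 0.0298; adjusted p = 0.473 with an estimated correlation). The calcium-binding protein gene Pvalb, a marker of proprioceptors, fell by 3.85 and the transcription factor gene Runx3 by 4.26, the latter at low counts. Nefh fell by 1.44. The transcription factor gene Maf was higher at 0.73, and with the GC and length offsets it stood at 0.32 (SE 0.14) and was not called. Calb1, the other gene that rose (1.29), stood at 0.51 (SE 0.38) with them and was not called either. With only genes of at least 5 CPM, the median of this list was -0.34 (camera adjusted p = 0.245).

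Other neuronal lists moved in both directions and were not called by camera. Of 14 nonpeptidergic genes 4 fell and 2 rose (camera adjusted p = 0.170): the itch-related receptor gene Mrgpra3 fell by 1.73, P2rx3 by 0.94 and Mrgprd by 0.76, while Cd55 and Runx1 were each higher at 0.46, and with the offsets stood at 0.13 (SE 0.089) and 0.03 (SE 0.10) and were not called. Without male B this list was called (median -0.28, adjusted p = 0.0253). Among 20 somatosensory channel genes 7 fell and 3 rose (adjusted p = 0.170). The acid-sensing channel gene Asic3 fell by 1.79 and Scn10a by 0.46, and the potassium channel gene Kcna1 was higher at 1.75. With the GC and length offsets this list was called (median -0.49, adjusted p = 0.0212; adjusted p = 0.516 with an estimated correlation). Piezo2, called higher at 0.32, stood at -0.05 with them. The Trk and p75 receptors had 2 lower genes, Ntrk2 (-1.03) and Ngfr (-0.99), and Sort1 was higher (0.49), with a camera adjusted p of 0.301 for the list. With the offsets Ngfr (-0.62, SE 0.26) and Sort1 (0.30, SE 0.16) were not called. Ntrk3, at -0.47 and not called without them, stood at -1.31 (SE 0.24) with them and was called lower. Of 7 itch neuron genes 4 were lower and Osmr was higher (0.66, and 0.24 with SE 0.22 and no call with the offsets; adjusted p of the list 0.428). Of 6 genes of C-fibre mechanoreceptors 3 were higher, among them P2ry1 (1.24), and 2 lower, Th (-0.86, and -0.45 with SE 0.20 and no call with the offsets) and Fam19a4 (-0.40, and -0.64 with them), with an adjusted p of 0.533. With the offsets Cdh9 (0.79 to 0.26, SE 0.20) and Slc17a8 (1.25 to 0.81, SE 0.37) were not called either, which leaves 1 gene higher and 1 lower.

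In the same libraries the synaptic vesicle genes were mostly lower, 8 of 15, with Syt1 alone higher (0.63). The SNARE gene Stx1a fell by 1.07 and Cplx1 by 0.76 (list median -0.47, camera adjusted p = 0.00545; adjusted p = 0.520 with an estimated correlation). With the GC and length offsets Stx1a stood at -0.62, Cplx1 at -0.32 and Syt1 at 0.27. Nuclear genes of oxidative phosphorylation showed 10 lower and 1 higher of 16, with Ndufv1 (-0.92, and -0.41 with the offsets) and Sdhb (-0.90, and -0.42) as examples (median -0.45, camera adjusted p = 0.00440; adjusted p = 0.473 with an estimated correlation). With the GC and length offsets the median was -0.22 (camera adjusted p = 0.120). Genes encoded in the mitochondrial genome went the other way: 7 of 8 tested were higher, among them mt-Nd1 (0.98, SE 0.077), mt-Cytb (0.77, SE 0.076) and mt-Nd5 (0.60, and 0.07 with SE 0.081 and no call with the offsets). Among the 7 was mt-Nd3, at 9.03, whose counts may follow a base that differs between the animals rather than its level, as described below. The median of the 8 genes was 0.92 (camera adjusted p = 4.03e-05; adjusted p = 0.473 with an estimated correlation). With only genes of at least 5 CPM, which leaves mt-Nd3 out, camera still called the list, and for fry no value without mt-Nd3 is given. With the offsets the median was 0.45 (camera adjusted p = 0.00916; adjusted p = 0.483 with an estimated correlation), mt-Nd1 stood at 0.55 and mt-Cytb at 0.41. Mitochondrial genes took 2.40% and 2.61% of the counts of female A and male A, and 1.30% and 1.32% of those of male B and male C.

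Schwann cell genes showed the largest list median, 2.48, with 11 of 13 genes higher (camera adjusted p = 1.04e-11; adjusted p = 0.473 with an estimated correlation). The myelin basic protein gene Mbp was higher at 1.99 (SE 0.25), Prx at 2.82 (SE 0.24) and the transcription factor gene Egr2, which drives myelination, at 3.13 (SE 0.30). Of 10 fibroblast genes 7 rose and none fell (median 2.26, camera adjusted p = 5.97e-11; adjusted p = 0.473 with an estimated correlation). Col3a1 was higher at 3.25 (SE 0.13), Col1a2 at 2.57 (SE 0.097), Col1a1 at 2.50 (SE 0.12) and the matrix protein gene Postn at 2.31 (SE 0.12; 1.42 with the GC and length offsets). The proteoglycan gene Dcn was called higher at 0.28, and with the GC and length offsets it was called lower at -0.52 (edgeR adjusted p = 0.00380). Satellite glia genes moved apart, with 6 higher and 4 lower of 12 (median 0.92, camera adjusted p = 0.0298; adjusted p = 0.473 with an estimated correlation). Cdh19 (2.83), Kcnj10 (2.20), Erbb3 (2.14) and Ednrb (1.62) rose, while Fbxo2 (-1.90), S100b (-1.52), Fabp7 (-1.30) and Glul (-0.59) fell. The satellite glia median was 1.04 without male B (camera adjusted p = 0.203) and 1.58 with only genes of at least 5 CPM (0.0541).

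The remaining cell type markers were scarce. Haemoglobin genes were higher, 3 of 5 erythroid genes passing, with Hbb-bt at 2.82 and Hbb-bs at 2.21. The erythroid median was 1.82 (camera adjusted p = 0.0298; adjusted p = 0.538 with an estimated correlation), and without male C it was 1.37 (camera adjusted p = 0.0585). These globin genes share between 58.3% and 86.9% of their 50-base words with each other and are uncertain. Of 8 endothelial and mural genes 4 were higher, each under 5 CPM in the embryo pair, among them Cdh5 (1.76) and Kdr (2.21, and 1.97 with SE 0.71 and no call with the GC and length offsets), and the list was not called (camera adjusted p = 0.533). No macrophage gene of the 5 tested was called (edgeR; camera adjusted p of the list 0.755). Of the sympathetic genes Gata2 alone was higher (2.96), at under 1 CPM in every library (camera adjusted p = 0.952). Acta1 was lower among the muscle genes (-0.97, and -0.44 with SE 0.24 and no call with these offsets) and Aqp4 among the spinal cord genes (-1.49), in lists with fewer than 3 tested members.

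**Figure D2:**
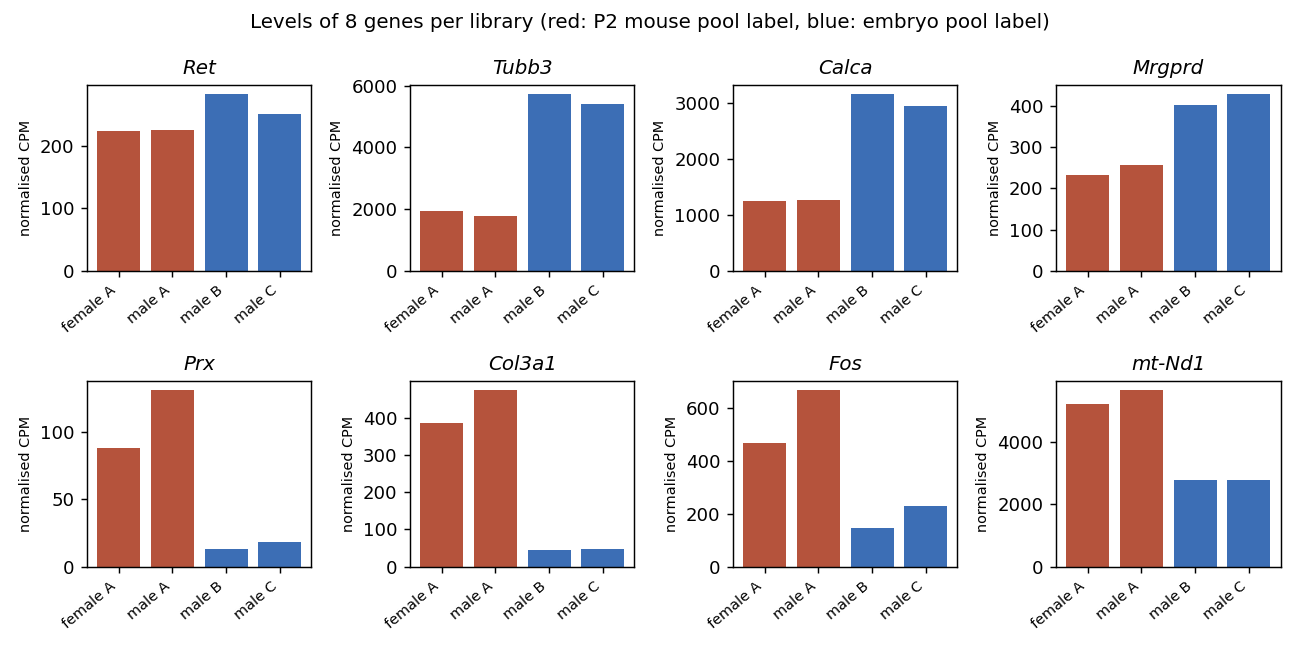
Normalised CPM of 8 genes (Ret, Tubb3, Calca, Mrgprd, Prx, Col3a1, Fos and mt-Nd1) in each of the 4 libraries, as bars from 0, with 1 bar per library and the pair described as P2 mouse in red and that described as embryo in blue. Mean levels in the P2-mouse and embryo pairs were 1866 and 5575 CPM for Tubb3, 110 and 15.6 CPM for Prx, and 223 and 266 CPM for Ret.

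Immediate early genes, which are induced within minutes by stimulation and also by tissue dissociation, were higher as a group. Of 18 genes 13 were higher and none lower, with a median of 1.34 (camera adjusted p = 2.22e-07; adjusted p = 0.473 with an estimated correlation). Fos stood at 469 and 670 CPM in female A and male A and at 148 and 230 CPM in male B and male C (log2 fold change 1.60, SE 0.23). Fosb was higher at 3.10, Nr4a1 at 2.46, Fosl2 at 2.30 and Egr1 at 2.20. The injury-induced transcription factor gene Atf3 was also higher (2.40, SE 0.37), as was Flrt3 (1.07), while Nts was lower (-0.69). With the GC and length offsets Flrt3 stood at 0.57 and Nts at -1.05. The injury and regeneration list was not called by camera (adjusted p = 0.224). Of 12 proliferation genes Top2a and Mki67 were higher and Cdk1 lower (camera adjusted p = 0.952), and Top2a (0.92 to 0.35, SE 0.14) and Mki67 (1.58 to 1.00, SE 0.36) were not called with the GC and length offsets.

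Of the X-linked genes that escape inactivation, 6 of 8 were higher in the P2-mouse pair, among them Ddx3x (1.66, SE 0.090; 1.01 with the GC and length offsets). The list median was 0.83 (camera adjusted p = 0.0112; adjusted p = 0.520 with an estimated correlation). With sex as a term, 2 were called and the median was 0.47 (camera adjusted p = 0.0644). It was 0.48 without female A (0.0583) and 0.47 with the GC and length offsets (0.0996). The 4 tested Y-linked genes were not called. With sex as a term 3 of them were higher in male A, and the list's median moved from 0.32 to 1.34 (camera adjusted p = 0.00200; adjusted p = 0.650 with an estimated correlation). Ddx3y stood at 173, 63.4 and 52.8 CPM in male A, male B and male C.

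Several lists had a median that changed sign with the GC and length offsets and were not called by camera. The medians of 20 ribosomal protein genes, 8 of them lower and Rps2 higher, were -0.28 and 0.02 without and with the offsets (camera adjusted p = 0.170 without them). Rpl8, lower at -0.56 without the offsets, stood at 0.01 with them. The medians of 14 axon guidance genes, of which 4 were higher, were 0.31 and -0.10 (adjusted p = 0.175). Robo2 moved from 0.74 to -0.08, while Nrp2 was higher at 1.76. The opioid and cannabinoid genes had medians of 0.15 and -0.52, with the opioid receptor gene Oprm1 higher (1.01) and Oprl1 lower (-1.18; camera adjusted p = 0.721). The sex hormone receptor list kept its sign, with medians of -0.51 and -0.91, and was not called either (camera adjusted p = 0.232 without the offsets). Of its 6 genes Gper1 (-1.59), Esr1 (-0.98, and -1.52 with the GC and length offsets) and Esr2 (-2.67) were lower. Esr2 stood at under 1 CPM in both pairs. With the offsets Esr2 was not called, though its value stayed at -2.54 (SE 0.89).

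**Figure D3:**
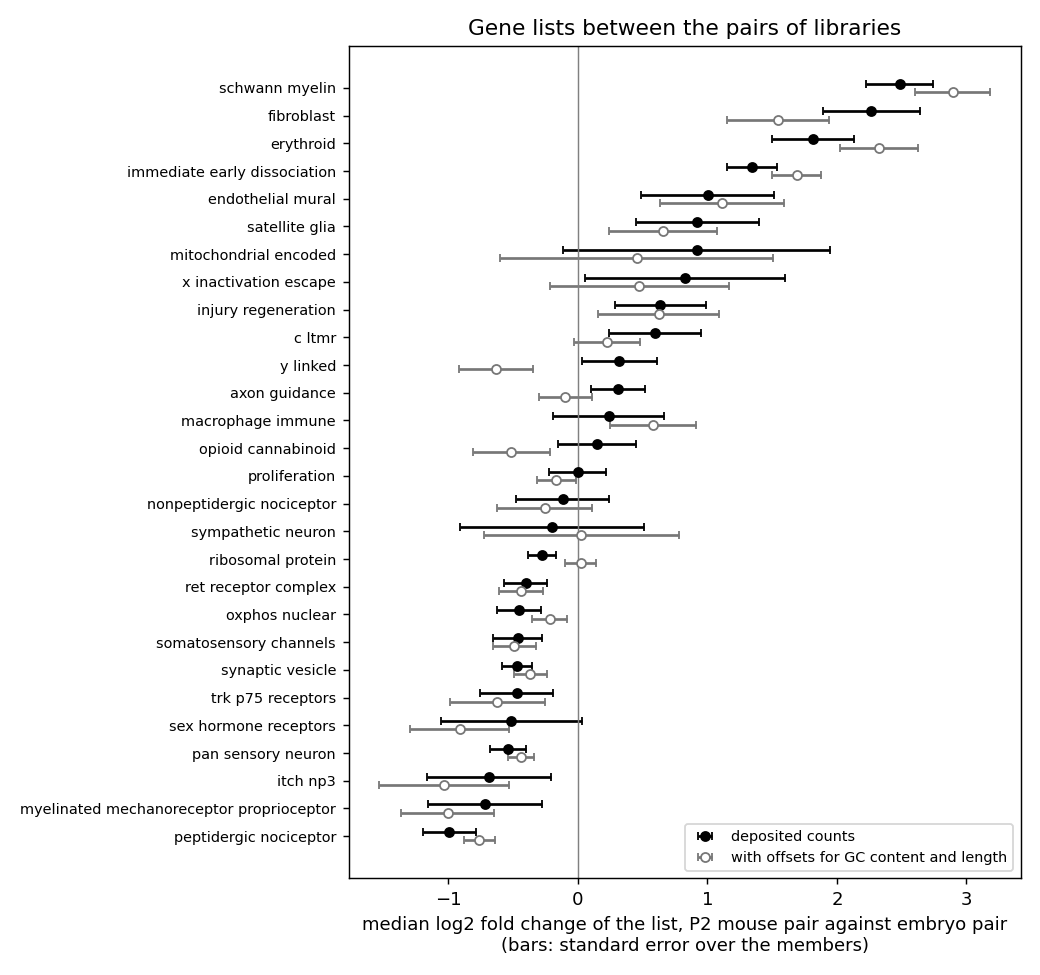
Median log2 fold change of each tested gene list between the P2-mouse pair and the embryo pair (horizontal axis, log2; bars, standard error over the members), from the deposited counts (filled circles) and with offsets for GC content and length (open circles). Schwann cell genes have the highest median in both (2.48 and 2.89); fibroblast genes stand at 2.26 and 1.55, and peptidergic nociceptor genes at -0.99 and -0.76.

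The same rule that was fixed for the sex comparison was used to name the largest changes between the pairs, which 5537 genes were eligible for. The largest rises were those of Rps3a3 (7.30, SE 0.22), the magnesium transporter gene Nipal1 (4.44, SE 0.31), the POU-domain transcription factor gene Pou3f1, which acts in Schwann cell myelination (4.31, SE 0.28), Serpina3f (4.30, SE 0.57) and Mpp6 (3.89, SE 0.19). Pdgfc, which encodes a growth factor for mesenchymal cells, Bcas1, Efhd1, the cell cycle inhibitor gene Cdkn1c and Pter followed, between 3.58 and 3.85. The largest falls were those of Chodl (-4.58, SE 0.48), Pvalb (-3.85, SE 0.39), Ldoc1 (-3.22, SE 0.36), the cytidine deaminase gene Cda (-2.99, SE 0.23) and Mab21l2 (-2.75, SE 0.26). Cdh3, Car3, Cpne6, Dnase1l3 and Htr5b, a serotonin receptor gene, followed, between -2.46 and -2.66. The edgeR adjusted p of these 20 genes was 0.00158 or less. Rps3a3 had 1899 and 1227 counts in female A and male A, and 11 and 8 in male B and male C. It shares 65.2% of its 50-base words with other annotated genes, Rps3a2 foremost, so its counts are uncertain. Rps3a1, which encodes the ribosomal protein S3A, had 1548 and 954 counts in female A and male A and 2303 and 2310 in male B and male C.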

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

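The tests with GC and length offsets, and all tests between the P2-mouse pair and the embryo pair, were chosen only after the result was seen. Between the female and the male libraries, edgeR called 0 genes higher and 0 lower (129 at an unadjusted p under 0.05). The counts higher and lower were 1 and 1 with no filter, 0 and 4 with the pool description as a term, 1 and 4 with that term and the offsets, and 1 and 4 with DESeq2. Relative log expression size factors, a mean of at least 5 CPM, the offsets alone, limma-voom and robust empirical Bayes gave 0 and 0. With a male left out the counts ran from 1 to 1935 higher and from 4 to 1681 lower, the highest without male A. No paired analysis was possible because the groups share only 1 replicate letter.

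Camera called 11 lists between female and male. In all it called 5 with no filter, 7 with a mean of at least 5 CPM, 6 with the pool description as a term, 6 with that term and the offsets, and between 9 and 13 with a male left out, lists newly called included. With the pool description as a term, proliferation and synaptic vesicle genes were newly called. With the pool description as a term many medians changed sign, called or not. Camera's direction reversed with a call in at least 1 of the fits for Schwann cell (0.36 to -0.63), fibroblast (0.95 to -0.077), immediate early (0.47 to -0.23), mitochondrially encoded (0.41 to -0.12) and synaptic vesicle genes (-0.14 to 0.17). Medians also changed sign for myelinated mechanoreceptor (-0.47 to 0.04), pan-sensory (-0.33 to 0.09), satellite glia (0.25 to -0.13), erythroid (0.67 to -0.29) and sex hormone receptor genes (-0.65 to 0.04), among others. With that term and the offsets they were -0.67, 0.0098, -0.32 and 0.15 for Schwann cell, fibroblast, immediate early and synaptic vesicle genes, 0.00083 for peptidergic nociceptor genes (from -0.77) and 0.028 for oxidative phosphorylation genes (from -0.33). For fibroblast genes the direction that camera gave reversed, not the sign of the median. The cause was not tested.

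Between the pairs, 3472 genes were higher and 3112 lower. The counts were 2064 and 1615 with sex as a term and 2151 and 2883 with the offsets, and ran from 1935 to 3630 and from 1681 to 3311 with a library left out. Other settings stayed within 1.5 times these counts. Lists called ran from 12 to 13 with a library left out. The median of the Y-linked list moved from 0.32 to 1.3425 without female A and to 1.338 with sex as a term, and camera's direction, down at first, reversed in both. Without male A, which leaves a female library with at most 2 counts per gene, it was -9.68 and camera's direction stayed down. With the offsets the values of Slc17a6 (0.26 to -0.21), Piezo2 (0.32 to -0.046), Rpl8 (-0.56 to 0.0072) and Robo2 (0.74 to -0.082) reversed, and the cause was not tested. The numbers below are of genes followed by the naming rule, and Dcn, not among them, was called higher at 0.28 and lower at -0.52 with the offsets. A fold counted as the same if its call and sign held, or if neither fit called it, whatever its value. It counted as stronger or weaker if a call was gained or lost, and as reversed only with a call in at least 1 fit. In the female comparison every fold counted as the same was called in neither fit, such as Ddx3x (0.92 to 0.05 with the pool description as a term). Over both comparisons 2843 gene folds were the same by this rule, 92 stronger, 163 weaker and 4 reversed. For list medians these numbers were 440, 14, 35 and 13. Of 492 levels in the males under other settings, 491 stayed within 1 SD, and Rpl4 moved from 755 to 744 CPM with plain totals. Most of these settings left out a male, which cannot move the mean of so few males by 1 SD. Those levels had to stay within it and tested nothing. Only the levels with plain totals could have moved further, so the count of 491 is no measure of how stable the levels are.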

Other observations

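The tests that compared the cell type lists with each other, and those that used shared words or the counts of mt-Nd3, were chosen only after the result was seen, and how to read the planned tests of each library against the other 3 was also written down after their counts were seen. A few genes were close to on in 1 pair of libraries and off in the other. With at least 20 counts in both libraries of a pair and at most 1 in each of the others, 9 genes met this rule for the pool descriptions, against 0 and 1 for the other ways of pairing. In the P2-mouse pair they included Casp4, an inflammatory caspase gene (52 and 53 counts in female A and male A, 0 and 1 in male B and male C), and Aim2, a sensor of cytosolic DNA (42 and 22, against 0 and 0). In the embryo pair they included Mas1, a receptor for angiotensin peptides (31 and 32 counts, against 0 and 0), Slc6a16 (21 and 34, against 0 and 0) and Clec18a (40 and 29, against 1 and 0). The others were 4933400F21Rik, Gm9968, mt-Nd3 and Gm28438.

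Between the female and the male libraries edgeR called 0 genes (129 at an unadjusted p under 0.05, 5 genes by DESeq2, 0 by limma-voom). Each of male A, male B and male C set against the other 3 libraries also gave 0, with 183, 628 and 362 genes at an unadjusted p under 0.05. With 0 genes for the female library, every split had to give as many (4 of 4, highest other 0), so this comparison decides nothing, and 4 splits are too few for a share under 0.05 in any case. Between the pairs parted by pool description 6584 genes were called, 1 of 3 splits giving as many (highest other 0), and 3 splits are too few as well.

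The difference between the pairs ran with GC content and transcript length. After offsets for both, 60.0% of the calls were kept in the same direction, so that bias may account for part of the calls and the share it accounts for stays open. Over 23 fibroblast and Schwann cell genes the median was 2.57 after the offsets (SE 0.256), from 2.48 to 2.89 for Schwann cell genes, which argues against it as the whole cause there, and from 2.26 to 1.55 for fibroblast genes (SE 0.395), so that part of the fibroblast difference may come from it. For immediate early genes the median was 1.69 after them (SE 0.192) and 1.34 before. A lower share of neurons that raised every other cell type alike would give these cell types like medians. After the offsets, over members of at least 5 CPM, the Schwann cell median (2.89, 13 genes) lay 1.76 (SE 0.535) above that of satellite glia (1.13, 11 genes). These were the highest and the lowest of the lists compared. The SEs in this paragraph are over genes, which are not independent replicates. The values show that these lists did not rise alike in these libraries, and do not settle the share of neurons. All 4 libraries carry the stage P2 and only the pool descriptions differ. Whether age, library batch or colony differed between the pairs is not given in the sources used here. On colony, mt-Nd3 took 99.3% of the counts of it and its copy in the P2-mouse pair and 0% in the embryo pair. A mitochondrial base that differs between the animals would give this, as described below. Whether age, batch or colony caused the other differences stays open and untested.

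Schwann cell genes had a lower median in the female library than in male A. GC content and length were argued against as the cause, since the median was -0.67 after the offsets (SE 0.054) and -0.63 before. A smaller share of all non-neuronal cells in the female could lower other cell types alike. The fibroblast median lay 0.56 (SE 0.106) above that of the Schwann cell genes. The SEs in this paragraph are over genes and measure no spread between animals or preparations, so this difference does not decide the question. The satellite glia median was -0.13 (SE 0.0718), and the erythroid, macrophage, and endothelial and mural lists rest mostly on genes under 5 CPM and decide nothing. With 1 animal on each side, sex and the preparation of each pool stay open and untested.

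Several mitochondrial genes had almost no counts. Those under 5 CPM, mt-Atp8 left out, shared at least 98.0% of their 50-base words with another annotated gene, and those above 100 CPM 62.2% at most, consistent with reads of several matches having been left out for these genes. Gm42418 (94.95%), Schip1 (90.4%) and Sept2 (83.9%) shared words as well and had many counts, so nothing is said of other genes. For mt-Atp8 the shared words were 0%, which argues against that explanation with annotated genes, while copies outside the annotation stay open. mt-Nd3 had 110 and 32 counts in female A and male A and 0 and 0 in male B and male C, whereas its copy Gm28438 had 0, 1, 54 and 51. The transcripts differ by 1 substitution in 345 bases (T3C, positions counted from 1 at the 5′ end of the mt-Nd3 transcript, the base of mt-Nd3 first), and mt-Nd3 took 99.3% of the counts of both genes in the P2-mouse pair (exact 95% interval 96.2% to 99.98%) and 0% in the embryo pair (upper limit 3.45%). That is consistent with a mitochondrial base that differs between the animals of the pairs, and the 0% argues against random assignment of reads that match both genes.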
